A study of Mus musculus with 2 samples.

How the data were processed

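Dissected cochleae of E16.5 mouse embryos were digested with 1 mg/mL collagenase/dispase for 30 min at 37 °C and passed through a 40 µm strainer, 8 cochleae per genotype. Libraries were made with a 10x Genomics 3′ kit. Per the labels' protocols the same kit version served both, while the sample descriptions name different versions. The deposited matrices hold raw UMI counts per gene and barcode for 32285 genes, without normalization. Per the submitters' processing notes, Cell Ranger 6.0.0 and mm10 were used. Per the file headers, the wild-type counts came from Cell Ranger 6.0.0 and the mutant counts from 5.0.1. How barcodes were called as cells is not given in the sources used here. The mutant matrix reaches down to 500 UMIs per barcode, and the 6500 wild-type barcodes stop well above that.

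Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs passed, 6440 in the wild type and 9373 in the mutant. Scrublet, run per library, called 0 and 0 doublets by its automatic threshold, so it had not worked. The fallback chosen beforehand removed the top-scored 0.8% per 1000 cells, 332 wild-type and 703 mutant barcodes. Both libraries were clustered together with scanpy 1.11.5 and igraph 0.11.9 under Python 3.11.15, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. No correction between libraries was made. Clusters were named from the 22 fixed marker sets by the mean of each marker's CPM over its highest cluster CPM, with at least 3 markers at 10 CPM. The scoring rule was settled after the data were seen. An earlier form let haemoglobin RNA name wild-type clusters erythroid, and the ranking of top genes was reset to compare with cells outside the own class. A cluster with more markers of another class than its own among its top 10 genes stayed unnamed, as did one with a median UMI count under 0.333 of its library's and none of its markers among those genes. Epithelial sub-clusters were made without any marker or listed gene and named in the same way, and the sub-clusters left unnamed remained in the epithelial class. The naming of sub-clusters was also revised after the data were seen, so that markers of every other class counted against a name and depth was measured against the whole library.

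Mixed barcodes were defined after the data were seen, as those with over 5 UMIs per 10000 from 28 genes of 5 lineages, without the class's own lineage. A first version of that gene set also held neuronal and further glial genes, and these were taken out because hair and supporting cells can express them. The main epithelial class keeps mixed barcodes, as planned. A limit of 10 per 10000, a common UMI floor at the wild-type minimum, and leaving out sub-clusters led by markers of other classes were added as alternatives at the same stage. For the common floor, barcodes were clustered and named anew.

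Counts were summed per library and class and given as CPM of the class total with exact Poisson 95% intervals, using scipy 1.17.1. Shares carry exact Clopper-Pearson 95% intervals. A share of 0 is given in the text with the limit of 3 counts, while the figures draw the exact interval. A gene list was summarised by the median over members with at least 10 UMIs of log2((CPM mutant + 1)/(CPM wild type + 1)), and counts of members at 2-fold or more use the same ratio. Its interval came from 2000 Poisson redraws, and its percentile from 10000 random lists matched on mean CPM. The 24 lists, the markers, the filters and most alternative settings were fixed before the data were examined. A gene on the Hedgehog target and core lists is not reported here. It was taken out of both list medians after the first values had been seen, so these lists are shorter than first set. Named genes had at least 100 UMIs over both libraries, at least 20 CPM in 1 library, and in the library where they were higher at least 0.5 of their CPM outside the class. They also had the same direction under CPM and median-of-ratios scaling, and were no mitochondrial, ribosomal protein, haemoglobin or sex chromosome genes. The 10 highest and 10 lowest ratios were taken in the epithelium and 5 of each in other classes with at least 200 barcodes per library. List members with the largest and smallest ratio among those with at least 30 UMIs served as examples, and Ptch1, Shh, Gli1, Emx2, Esrrb, Kcne1 and Kcnq1 were always given. Other list members given as examples in the text were chosen after their values were seen. Gene coordinates came from GENCODE vM21 on the GRCm38 (mm10) assembly, in which 32158 of the 32285 gene identifiers were found.

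The ratios, intervals and list medians were tested on simulated data for the epithelial comparison, with 12256 genes of which 200 had known folds. Counts were independent Poisson draws from 1 profile shared by both libraries, so the simulation covers counting error only. It holds no spread between cells or libraries and no mixed barcodes, and intervals built for Poisson counts were bound to do well in it. All 50 genes simulated 2-fold higher and all 50 simulated 2-fold lower came out in the right direction, with median log2 ratios of 1.00 and -0.93. The interval held the true ratio for 95.7% of unchanged genes, for 90% of genes simulated 2-fold higher and as many at 4-fold, and for 96% of those 2-fold and 94% of those 4-fold lower. Of 50 unchanged lists, 46 fell within the middle 95% of random lists. Alternatives covered the barcode filter, doublets, cluster resolution, scaling, pseudocount, minimum UMIs of a member, equal weight per cell, cells with Epcam or Cdh1 in place of clusters, and mutant sub-clusters weighted to wild-type numbers. That weighting could use only 5 sub-clusters with at least 20 barcodes in both libraries, which hold 513 of the 1705 wild-type epithelial barcodes.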

Results

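Single-cell RNA sequencing was done on cochleae of mouse embryos at E16.5, with 1 library from wild-type embryos and 1 from embryos carrying Emx2-Cre and floxed Ptch1. Ptch1 encodes the Hedgehog receptor that holds the pathway off when no ligand is bound, and Cre driven from Emx2 is meant to remove it in Emx2-expressing cells. Each library pooled 8 cochleae, and the series asks how Hedgehog signalling bears on marginal cells and the stria vascularis, the secretory tissue of the cochlear lateral wall. With 1 library per genotype no difference has a replicate check, no test was run, and every interval covers counting error only. The wild-type library held 6500 barcodes with 61130806 UMIs and the mutant library 100135532 UMIs over more barcodes. The median was 7333 UMIs per barcode in the wild type and 6524.5 in the mutant. Below the shallowest wild-type barcode lay 4705 mutant barcodes (38.2%). After filtering, 6108 wild-type and 8670 mutant barcodes were kept.

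Epithelial, mesenchymal and glial cells were the classes with enough barcodes in both libraries to compare expression. The cochlear epithelium took 27.9% of the 6108 wild-type barcodes (1705, 95% interval 26.8 to 29.1) and 23.8% of the 8670 mutant barcodes (2066, 22.9 to 24.7). Its barcodes were shallower in the mutant, with medians of 7510 UMIs in the wild type and 3695.5 in the mutant. Mesenchymal cells took 43.2% of the 6108 wild-type barcodes (2639, 95% interval 42.0 to 44.5) and 50.2% of the 8670 mutant barcodes (4351, 49.1 to 51.2). Neurons took 5.62% of the 6108 wild-type barcodes (343, 95% interval 5.05 to 6.22) and 0.784% of the 8670 mutant barcodes (68, 0.610 to 0.993), and intermediate cells or melanocytes, the pigment cells of the stria, took 0.737% of the 6108 wild-type barcodes (45, 95% interval 0.538 to 0.985) and 0.265% of the 8670 mutant barcodes (23, 0.168 to 0.398). Unnamed clusters held 9.33% of wild-type and 14.6% of mutant barcodes. Above a UMI floor common to both libraries, chosen after seeing the data, the epithelial shares were 23.6% and 15.5%, the neuronal shares 5.76% and 0.990% and the intermediate cell shares 0.720% and 0.301%. That floor removed no wild-type barcode, but clusters were made and named anew, so the wild-type shares moved through the clustering. With sub-clusters led by markers of other lineages left out, also a later choice, the epithelial shares were 16.3% in the wild type and 23.4% in the mutant, and at Leiden resolution 2, a planned setting, 20.0% and 23.4%. Which library had the larger epithelial share thus depends on the settings. Dissection, digestion and the UMI floor can each set such shares.

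Transcripts of several lineages met in many wild-type epithelial barcodes. Over 5 UMIs per 10000 came from genes of other lineages in 62.1% of wild-type and 10.2% of mutant epithelial barcodes. Among neurons the share was 64.7% in the wild type and 0 of 68 barcodes in the mutant, which allows a share of up to 4.41%, and among mesenchymal cells 1.10% and 2.30%. Of the neuronal barcodes, 121 in the wild type and 68 in the mutant lay at or under the limit. Haemoglobin transcripts made up 0.856% of UMIs in wild-type epithelium and 0.0248% in mutant epithelium. Epithelial list medians are therefore given also without these mixed barcodes, which left 646 wild-type and 1855 mutant barcodes. That limit was set after the data had been seen.

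**Figure D1:**
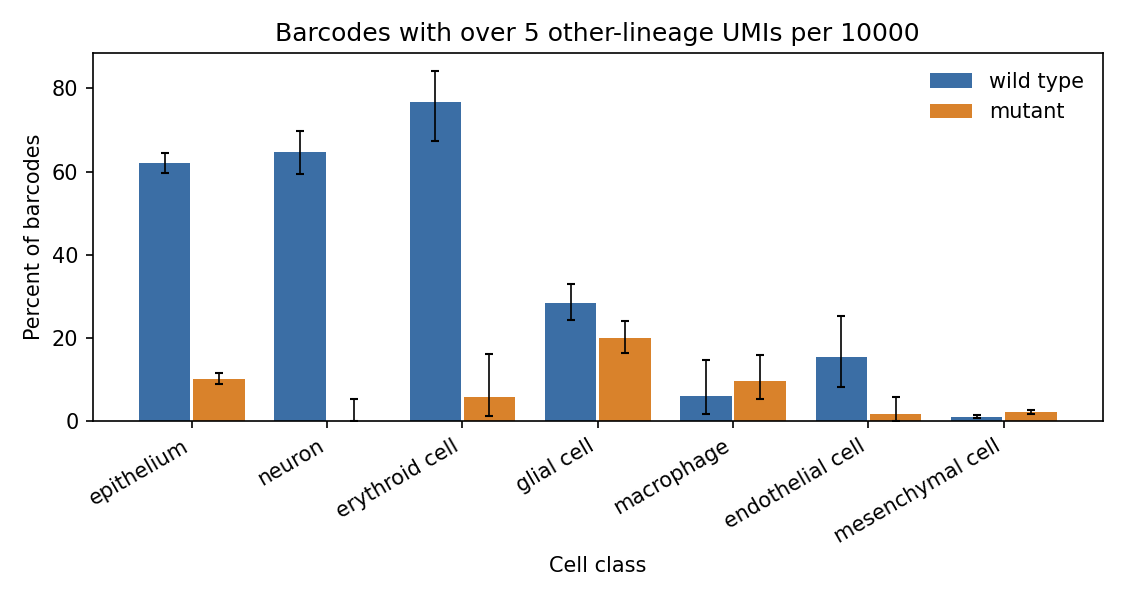
Percent of barcodes in each plotted cell class (vertical axis) with over 5 UMIs per 10000 from genes of other lineages, by library, with exact binomial 95% intervals. Not drawn are intermediate cells, at 6.67% in the wild type and 26.1% in the mutant, and pericytes or smooth muscle cells, at 98.3% and 97.3%. For the latter no lineage was set as their own. In the epithelium the share was 62.1% in the wild type and 10.2% in the mutant.

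The targeted gene was measured first. In the epithelium, Ptch1 stood at 30.1 CPM (95% interval 27.6 to 32.8, 524 UMIs) in the wild type and 184 CPM (178 to 190, 3739 UMIs) in the mutant. The libraries count tags near transcript 3′ ends, and the labels do not say which exons are floxed, so this value checks neither the deletion nor the labels. In mesenchyme, Ptch1 stood at 20.0 CPM in the wild type and 22.5 CPM in the mutant, and in glia at 97.5 CPM in the wild type and 64.3 CPM in the mutant. Emx2, the gene whose expression drives Cre, stood at 17.5 CPM in the wild type and 32.0 CPM in the mutant in the epithelium, against 0.177 and 0.254 CPM in mesenchyme and 0.330 and 0.239 CPM in glia. On mm10, the build the submitters' processing notes name, Ptch1 lies on chromosome 13, 63508328 to 63573598, and Emx2 on chromosome 19, 59458372 to 59465357.

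The Hedgehog readout was higher in mutant epithelium and about level in mesenchyme. Gli1, a transcription factor induced by the pathway, stood at 1.95 CPM (95% interval 1.35 to 2.73, 34 UMIs) in the wild type and 20.0 CPM (18.1 to 22.0, 405 UMIs) in the mutant in the epithelium. Hhip, a secreted Hedgehog antagonist that the pathway induces, stood at 1.90 CPM (95% interval 1.31 to 2.66, 33 UMIs) in the wild type and 14.8 CPM (13.2 to 16.6, 300 UMIs) in the mutant. Here and below, log2 ratios and counts of members at 2-fold or more are taken after adding 1 CPM to both values, which draws ratios of low-count genes towards 0. The median log2 ratio of mutant over wild type across these genes and Ptch1 was 2.57 (95% counting interval 2.46 to 2.78, percentile 99.99 of matched random lists). All 3 were at least 2-fold higher in the mutant, and without mixed barcodes the median was 3.27. With 3 genes the median is the value of the middle gene, which was the targeted gene Ptch1 for 2.57 and Gli1 for 3.27. In all epithelial barcodes the log2 ratios of Gli1 and Hhip were 2.83 and 2.45. In mesenchyme and glia the middle gene was again Gli1. In mesenchyme the median was -0.0494 (95% counting interval -0.32 to 0.18, percentile 28.6 of matched random lists), with Gli1 at 5.45 and 5.24 CPM in wild type and mutant, and Hhip lower at 10.2 and 4.02 CPM. In glia the median was -0.28 (95% counting interval -0.77 to 0.19, percentile 14.1 of matched random lists). Shh itself had 1 UMI in each epithelium, too few to compare. Gli1 lies on chromosome 10, 127329882 to 127341974, and Hhip on chromosome 8, 79965851 to 80058006.

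**Figure D2:**
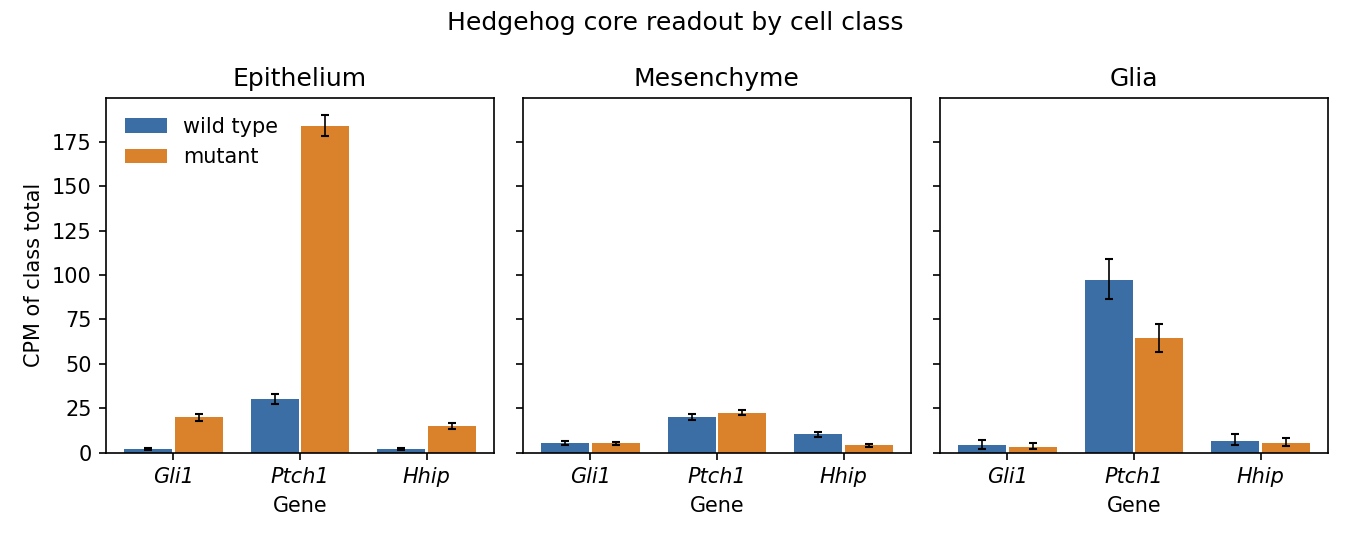
CPM of the class total (vertical axis) of 3 Hedgehog readout genes in epithelium, mesenchyme and glia, by library, with exact Poisson 95% intervals. Mutant epithelium stood above the wild type for each gene, with Ptch1 at 30.1 and 184 CPM in wild type and mutant.

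The wider list of Hedgehog targets had members on either side in the epithelium. Its median was near 0, at -0.0131 (95% counting interval -0.0500 to 0.0233, percentile 40.4 of matched random lists), with 4 of 11 measured members at least 2-fold higher in the mutant and 4 at least 2-fold lower. With mixed barcodes left out the median was 0.46, with 4 of 10 at least 2-fold higher and 1 lower. Ccnd1, a G1 cyclin, stood at 226 and 701 CPM in wild type and mutant. Mycn, a proliferation-linked transcription factor, stood at 24.5 and 48.5 CPM. The lowest member was Foxd1, a mesenchymal transcription factor in this tissue, at 20.7 and 2.96 CPM, and its log2 ratio of -2.46 was -1.08 without mixed barcodes. Ccnd2 went from -1.50 to 0.30 in the same comparison. Receptor and transducer genes of the pathway had a median of 0.22 (95% counting interval 0.0450 to 0.29, percentile 94.2 of matched random lists), and 0.14 without mixed barcodes. With 1 CPM added, none of the 14 measured reached 2-fold either way, while Dhh, a Hedgehog ligand, stood at 1.95 and 0.640 CPM in wild type and mutant.

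Marginal cells line the stria and secrete potassium into the endolymph, and most of their listed genes were lower in mutant epithelium. The list median was -0.56 (95% counting interval -0.73 to -0.34, percentile 0.06 of matched random lists), with 6 of 16 measured members at least 2-fold lower and 0 at least 2-fold higher with 1 CPM added. Esrrb, a nuclear receptor needed for marginal cell identity, stood at 7.82 CPM (95% interval 6.56 to 9.24, 136 UMIs) in the wild type and 0.739 CPM (0.414 to 1.22, 15 UMIs) in the mutant. Kcne1 and Kcnq1, which form the marginal cell potassium channel, stood at 5.00 and 0.788 CPM and at 3.33 and 1.23 CPM in wild type and mutant. At low CPM, Bsnd, a chloride channel subunit, stood at 0.690 and 0.0493 CPM and Atp13a5 at 0.287 and 0.838 CPM. Hmx2, an otic homeobox gene, stood at 3.74 and 0.443 CPM. Lmx1a, a homeobox gene of the non-sensory duct, had the highest ratio in the list with 1 CPM added, at 10.9 and 18.8 CPM. Without mixed barcodes the median was -0.56, with 3 of 15 members at least 2-fold lower. The median was closer to 0, at -0.20, in cells chosen by Epcam or Cdh1 and at -0.25 with 5 CPM added, and it was above 0 under a weighting of shared sub-clusters that leaves out most wild-type barcodes. Without mixed barcodes the log2 ratios of Kcne1 and Kcnq1 were -0.89 and -0.56, and Esrrb rested on 32 and 14 UMIs with a log2 ratio of -1.43. Esrrb lies on chromosome 12, 86361117 to 86521628, Kcne1 on chromosome 16, 92345982 to 92359468 and Kcnq1 on chromosome 7, 143106362 to 143427042.

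At an equal depth of 2000 UMIs, a UMI of Esrrb, Kcne1 or Kcnq1 was found in 42 of 1705 wild-type barcodes (2.46%, 95% interval 1.78 to 3.32) and 9 of 1379 mutant barcodes (0.653%, 0.299 to 1.24). The thinning left out 0 wild-type and 687 mutant barcodes as too shallow. Over 1000 repeated draws the count ran from 29 to 59 in the wild type and from 1 to 15 in the mutant. The background in mesenchymal cells was 0 of 2639 wild-type barcodes, which for that draw alone allows a share of up to 0.114%, and 1 of 3873 mutant barcodes. Over the repeated draws the medians were 2 and 1, with at most 5 and 2 in any draw. Unthinned, 5 of the 2639 wild-type mesenchymal barcodes (0.189%) had such a UMI. Among barcodes deep enough to thin, median depths before thinning were 7510 and 8286 UMIs in the epithelium and 7401 and 9174 in mesenchyme. Over all kept barcodes of each class the medians were 7510 and 3695.5 UMIs in the epithelium and 7401 and 8611 in mesenchyme. Unthinned, the epithelial shares were 7.51% and 1.55%. Without mixed barcodes, the shares at 2000 UMIs were 7 of 646 wild-type barcodes (1.08%, 95% interval 0.437 to 2.22) and 4 of 1309 mutant barcodes (0.306%, 0.0833 to 0.781), and these intervals overlap. Over repeated draws these counts ran from 1 to 14 and from 2 to 12. Unthinned and without mixed barcodes the shares were 31 of 646 wild-type barcodes (4.80%, 95% interval 3.28 to 6.74) and 28 of 1855 mutant barcodes (1.51%, 1.01 to 2.17), and these intervals do not overlap, though depths differ there. Leaving out mixed barcodes took Esrrb from 136 to 32 wild-type UMIs, though it stood at only 0.407 CPM outside the wild-type epithelium. That step thus also removed wild-type barcodes with these transcripts, so the overlap cannot decide whether the shares differ.

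Most hair cell genes were lower in mutant epithelium, by very different amounts, while other members of the sensory list went either way. The sensory list had a median of -0.73 (95% counting interval -0.90 to -0.60, percentile 0 of matched random lists), with 8 of 16 members at least 2-fold lower and 1 at least 2-fold higher. Pou4f3, a transcription factor that hair cells need to survive, stood at 32.5 CPM (95% interval 29.9 to 35.3, 566 UMIs) in the wild type and 1.23 CPM (0.797 to 1.82, 25 UMIs) in the mutant. Atoh1, which specifies hair cells, stood at 11.8 and 3.25 CPM in wild type and mutant, and Gfi1, another hair cell transcription factor, at 1.95 and 0.197 CPM. Myo6 and Myo7a, hair cell myosins, stood closer, at 83.4 and 40.5 CPM and at 6.84 and 4.78 CPM. Fgfr3 and Prox1, genes of supporting cells, stood at 14.8 and 1.97 CPM and at 23.2 and 5.22 CPM. Sox2, which marks the prosensory domain, stood at 107 and 152 CPM, and Hey2, a Notch and FGF effector there, at 9.31 and 54.7 CPM. Jag1 and Lfng, Notch pathway genes of the same domain, stood at 133 and 121 CPM and at 6.67 and 5.17 CPM. Fgf20, a prosensory growth factor on the FGF list, stood at 4.20 and 32.8 CPM. The list median was -0.96 without mixed barcodes, but -0.29 in cells chosen by Epcam or Cdh1, -0.35 with 5 CPM added and -0.44 over members with at least 50 UMIs. It was also closer to 0 under a weighting of shared sub-clusters that leaves out most wild-type barcodes. Without mixed barcodes the log2 ratio of Pou4f3 was -4.29 and that of Hey2 2.44.

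Genes of the cochlear roof were mostly higher in mutant epithelium. The list median was 0.54 (95% counting interval 0.49 to 0.63, percentile 99.99 of matched random lists), with 5 of 12 members at least 2-fold higher and 2 at least 2-fold lower. Otx2, a homeobox gene of the roof, stood at 5.23 CPM (95% interval 4.21 to 6.42, 91 UMIs) in the wild type and 56.2 CPM (53.0 to 59.5, 1140 UMIs) in the mutant. Vmo1, a marker of Reissner's membrane, stood at 2.30 and 34.5 CPM in wild type and mutant, and Oc90, an otoconial matrix protein, at 1291.5 and 3083 CPM. Enpep and Rspo3 went the other way, at 25.5 and 4.58 CPM and at 25.8 and 5.12 CPM. Without mixed barcodes the median was 0.49. Lateral duct genes had a median of -0.35 (95% counting interval -0.62 to -0.0714, percentile 0.595 of matched random lists), and -0.20 without mixed barcodes. Bmp4, a signal made at the lateral edge, stood at 129 and 18.1 CPM. The tectorial membrane list had a median of 0.31 (95% counting interval 0.19 to 0.42, percentile 99.7 of matched random lists), which was -0.26 without mixed barcodes. Its members went both ways, with 5 of 11 at least 2-fold lower and 1 higher. In that list Crabp1, a retinoic acid binding protein, was lowest at 228 and 34.6 CPM, and Tectb, a tectorial membrane protein, highest at 317 and 644 CPM.

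Cell cycle genes were higher in mutant epithelium. The S phase list had a median of 0.80 (95% counting interval 0.73 to 0.85, percentile 100 of matched random lists) and the G2 and M phase list of 0.97 (95% counting interval 0.93 to 1.03, percentile 100 of matched random lists). No member of either list was 2-fold lower in the mutant, and 5 of 22 and 9 of 21 were at least 2-fold higher. Ccna2, a cyclin of S and G2 phases, stood at 21.6 and 61.2 CPM in wild type and mutant, and Mki67, a proliferation marker, at 74.8 and 148 CPM. E2f8, an E2F family transcription factor, stood at 3.51 and 11.9 CPM. The medians were 1.27 and 1.50 without mixed barcodes, and 0.58 and 0.75 in cells chosen by Epcam or Cdh1. They were also closer to 0, though still above it, under a weighting of shared sub-clusters that leaves out most wild-type barcodes. In mesenchyme the medians were 0.12 and 0.13.

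**Figure D3:**
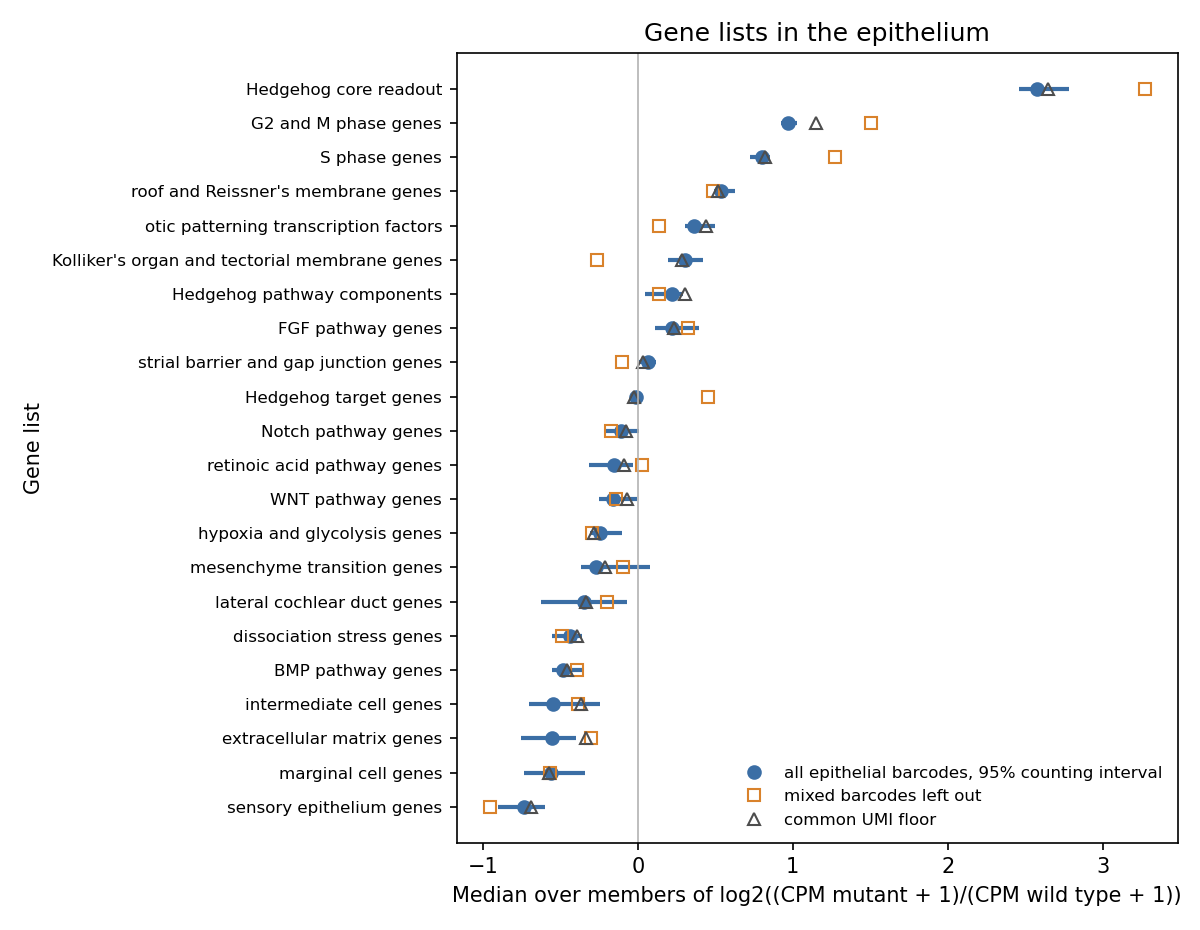
Median log2 ratio of mutant over wild-type CPM (horizontal axis) for gene lists in the epithelium. The haemoglobin and sex chromosome lists, with medians of -5.00 and 0.24, are not drawn. Bars are 95% counting intervals and the other symbols leave out mixed barcodes or apply a common UMI floor. The Hedgehog core readout had the highest median, 2.57, and the sensory list had -0.73.

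Among 6200 epithelial genes that met the size rule, those with the highest mutant ratios included the roof genes Vmo1 and Otx2. Gpld1, a phospholipase, stood at 2.13 and 47.7 CPM in wild type and mutant, Glb1l2 at 4.08 and 76.6 CPM and Adamts18, a metalloprotease, at 3.68 and 59.4 CPM. Spon1, an extracellular matrix protein, stood at 4.37 and 71.8 CPM, Barx2, a homeobox gene, at 0.919 and 24.8 CPM and Lor at 17.1 and 160 CPM. Cldn22, a tight junction gene, stood at 2.30 and 23.7 CPM. The histone gene Hist1h2ap stood at 48.4 and 584 CPM in the epithelium and at 145 and 881 CPM in mesenchyme. The lowest ratios included those of hair cell genes, Pou4f3 among them. Ccer2 stood at 173 and 16.7 CPM, Pcp4 at 79.9 and 9.61 CPM, Rasd2 at 25.3 and 1.63 CPM, Grp at 23.0 and 1.63 CPM and Grxcr1, a stereocilium gene, at 20.5 and 0.690 CPM. Lhfpl5, part of the mechanotransduction channel, stood at 25.0 and 0.591 CPM, and Pvalb, a calcium-binding protein also among the leading genes of a neuronal cluster, at 61.0 and 1.23 CPM. Pvalb stood at 29.7 and 1.27 CPM without mixed barcodes, and outside the epithelium the wild type had 106 CPM. Col1a1, a fibroblast collagen, and Cldn5, an endothelial junction gene, also ranked among the lowest, at 23.3 and 1.08 CPM and 25.2 and 0.788 CPM. Their log2 ratios of -3.55 and -3.87 were -0.36 and -0.48 without mixed barcodes.

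Hair cell-like and lateral epithelial sub-classes came almost entirely from the wild type, and the other named sub-classes held barcodes of both libraries. Within the medial, prosensory and roof-like sub-classes, however, the libraries often lay in different sub-clusters. Sub-clusters were made without any listed gene and named from the fixed markers. Hair cell-like sub-clusters held 121 wild-type barcodes (7.10%, 95% interval 5.92 to 8.42) and 2 in the mutant (0.0968%, 0.0117 to 0.349). Lateral epithelium-like barcodes numbered 163 in the wild type (9.56%) and 0 of 2066 in the mutant, which allows a share of up to 0.145%. Roof-like sub-clusters held 106 wild-type barcodes (6.22%, 95% interval 5.12 to 7.47) and 587 in the mutant (28.4%, 26.5 to 30.4). Prosensory or supporting cell-like sub-clusters held 73 wild-type barcodes (4.28%, 95% interval 3.37 to 5.35) and 282 in the mutant (13.6%, 12.2 to 15.2). One of them held 64 wild-type and 74 mutant barcodes, and the other 9 and 208. The latter scored 0.496 as prosensory against 0.395 as lateral epithelium, with 1 marker of each among its 10 leading genes. Medial epithelium-like sub-clusters, the largest named sub-class, held 458 wild-type barcodes (26.9%, 95% interval 24.8 to 29.0) and 593 in the mutant (28.7%, 26.8 to 30.7). By sub-cluster the wild-type and mutant counts were 194 and 0, 97 and 1, 104 and 200, 27 and 175, and 36 and 217. That with 27 and 175 was led by cell cycle genes, with no medial marker among its 10 leading genes. Of the mutant roof-like barcodes, 205 and 301 lay in shallow sub-clusters with medians of 1801 and 1853 UMIs, and most of the 10 leading genes of the latter were cell cycle genes. Those sub-clusters held 3 and 0 wild-type barcodes, and 91 wild-type barcodes lay in another with 9 mutant ones. No sub-cluster was named marginal cell-like under the naming rule revised after the data were seen. The nearest, with 60 wild-type barcodes and 1 in the mutant, had Esrrb among its 10 leading genes but was led by the melanocyte genes Dct and Pmel. It scored highest as strial marginal cell, at 0.695 with 9 markers above the mean over sub-clusters, against 0.241 for the next class. Sub-clusters left unnamed because markers of another class led them held 45.2% of wild-type and 2.03% of mutant epithelial barcodes, and those left unnamed for low depth 0.821% and 27.1%. Of the former, those with 151, 145, 61 and 71 wild-type and no mutant barcodes scored best as prosensory or supporting cells. So did low-depth ones with 183 and 89 mutant barcodes. Others scored best as medial, with 282 wild-type and 41 mutant barcodes and with 10 and 288. The prosensory and medial shares thus depend on the naming rule. Above the common floor the counts in wild type and mutant were 85 and 3 for hair cell-like, 68 and 1 for lateral, 119 and 222 (8.24% and 20.5%) for roof-like, 602 and 638 (41.7% and 58.9%) for medial and 76 and 218 for prosensory barcodes. That floor removed no wild-type barcode, but clusters and sub-clusters were made and named anew. The changes in wild-type counts therefore come from the new clusters and names, not from depth. Mixed barcodes made up 59.5% of the wild-type hair cell-like, 57.1% of the lateral and 69.8% of the roof-like barcodes, against 12.6% of the mutant roof-like barcodes. A sub-cluster mostly of 1 library is not shown to be a cell type.

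**Figure D4:**
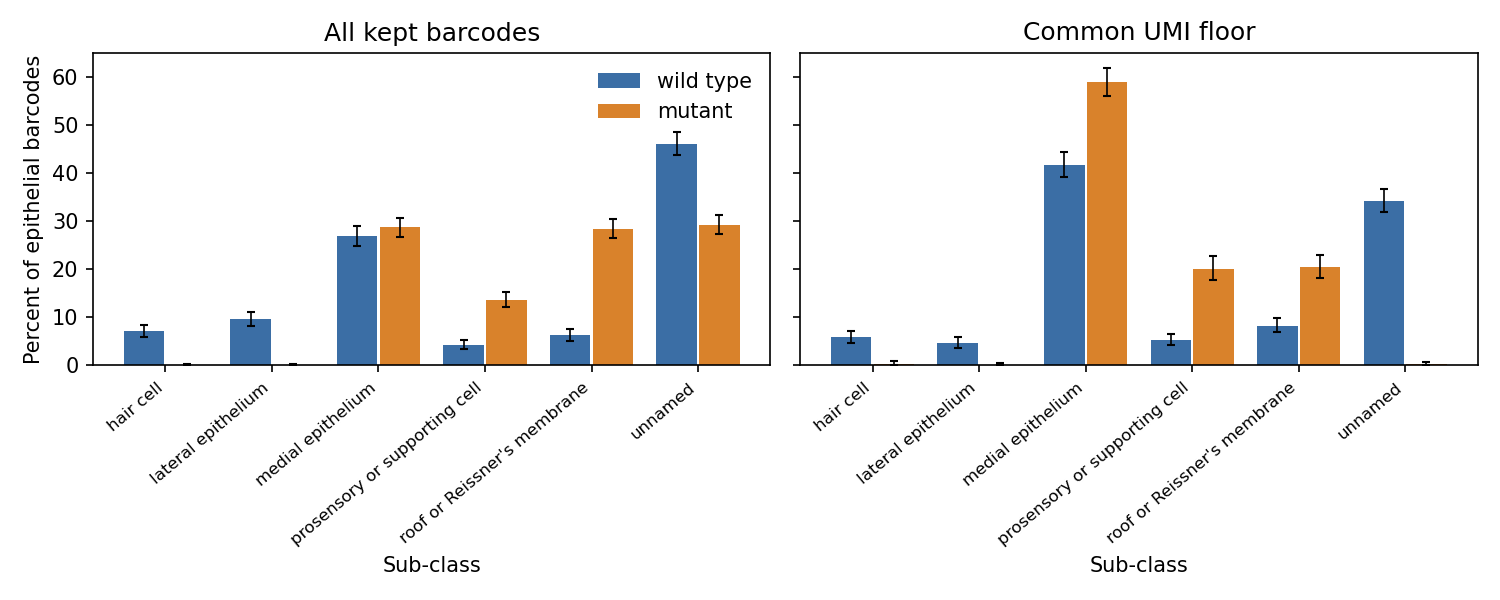
Percent of epithelial barcodes (vertical axis) in each sub-class by library, with exact binomial 95% intervals, for all kept barcodes and above the common UMI floor. Hair cell-like barcodes took 7.10% of the wild-type and 0.0968% of the mutant epithelium.

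In mesenchyme most lists lay close to level, and haemoglobin genes had the largest median, 0.82, though it was -2.75 when barcodes above the common UMI floor were clustered anew. That floor removed no wild-type barcode, yet the mesenchymal class then held 2800 wild-type barcodes, against 2639. Values above the floor in this paragraph thus differ in class membership as well as depth. Strial barrier and gap junction genes had the lowest median, -0.35 (95% counting interval -0.40 to -0.0445, percentile 0.025 of matched random lists), and -0.61 above that floor. Notch pathway genes had a median of 0.26 (percentile 99.7 of matched random lists), and 0.16 above the floor. Extracellular matrix genes had a median of -0.30 (95% counting interval -0.32 to -0.25, percentile 0 of matched random lists), with Col1a1 at 54.2 and 26.8 CPM in wild type and mutant. Retinoic acid genes had a median of -0.18 (95% counting interval -0.34 to -0.11, percentile 0.3 of matched random lists), with the retinaldehyde dehydrogenase Aldh1a1 at 3.86 and 0.0763 CPM. By the size rule, Penk, an opioid peptide precursor, stood at 21.6 and 107 CPM and Ucma, a cartilage gene, at 21.1 and 4.30 CPM. The other genes named there differed in the same direction in glia: Pianp, Mpnd, Gm10076, Hist1h2ap, Hist1h2ab, Hist1h2an, Hist1h4d and Snhg3. Pianp stood at 6.34 and 40.9 CPM in mesenchyme, with log2 ratios of 2.51 there, 3.98 in glia and 2.71 in epithelium. Mpnd stood at 6.92 and 64.9 CPM in mesenchyme and 8.59 and 58.3 CPM in glia, and Gm10076 at 513 and 2101 CPM and 461 and 2054 CPM. Hist1h2ab stood at 113 and 25.3 CPM in mesenchyme, Hist1h2an at 40.8 and 9.48 CPM, Hist1h4d at 188 and 50.6 CPM and Snhg3 at 65.6 and 16.7 CPM. The file headers name different Cell Ranger versions for these libraries, 6.0.0 for the wild type and 5.0.1 for the mutant.

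In glia, S phase genes were slightly higher and BMP pathway genes lower in the mutant. The G2 and M phase list had a median of -0.17 (95% counting interval -0.22 to -0.0682, percentile 1.93 of matched random lists), which was -0.0830 without mixed barcodes, and none of its members reached 2-fold. The roof list, with 5 of 12 members measured, had a median of 0.72 (95% counting interval 0.42 to 1.09, percentile 99.9 of matched random lists). The S phase list had a median of 0.31 (95% counting interval 0.22 to 0.39, percentile 100 of matched random lists) and the BMP list of -0.44 (95% counting interval -0.55 to -0.30, percentile 0 of matched random lists). With mixed barcodes left out these were 0.39 and -0.32. Bmp4 stood at 17.2 and 7.65 CPM in wild type and mutant, and Smad6, an inhibitor of BMP signalling, at 15.2 and 6.69 CPM. The size rule also named Syt1, a synaptic vesicle gene, at 3.63 and 32.3 CPM, and Pbld1 at 6.28 and 29.2 CPM. The histone genes Hist1h2af, Hist1h3e and Hist1h3c stood at 26.8 and 4.78 CPM, at 55.8 and 13.6 CPM and at 95.5 and 23.9 CPM. Hist1h4d and Hist1h2ab stood at 261 and 59.0 CPM and at 122 and 27.3 CPM, and Hist1h2ap at 133 and 853 CPM.

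The intermediate cell class was named from many of the listed identity genes, so cells that had lost them could fall outside it. Within the class, intermediate cells of both libraries expressed these genes at similar levels. Their list had a median of -0.13 (95% counting interval -0.20 to 0.00580, percentile 28.0 of matched random lists), with 11 of 14 measured members within 2-fold. Dct, a melanin synthesis enzyme, stood at 18592 and 17637 CPM in wild type and mutant, and Mitf, the transcription factor of melanocytes, at 475 and 503 CPM. Kcnj13, a potassium channel, stood at 44.7 and 123 CPM, and Mlana, a melanosome protein, at 818 and 344 CPM. These values rest on 45 wild-type and 23 mutant barcodes.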

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

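The tests of explanations here were all chosen after the results had been seen.

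Hhip stood out because its difference between genotypes had opposite directions by cell class. Its log2 ratio of mutant over wild type was 2.45 in epithelium and -1.16 in mesenchyme. The difference between the classes was not tested.

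Barcodes that the cell filter left out also carried Hedgehog readout transcripts. In the mutant, 393 UMIs of Gli1, Ptch1 and Hhip gave 89.4 CPM (95% interval 80.8 to 98.7) over 2953 barcodes. The 60 wild-type barcodes left out gave 6.87 CPM (2.23 to 16.0). The sets failed for unlike reasons: 0 wild-type but 2339 mutant barcodes had too few UMIs. In the wild type 42 had too few genes and 18 too high a mitochondrial share. The cell types in these barcodes were not compared.

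For the higher Hedgehog readout in mutant epithelium, RNA from other cells would need the median to fall below 1 in barcodes with few other-lineage UMIs, and it was 3.27 there. That test could hardly come out otherwise, since wild-type cells outside the epithelium had more Gli1 and Hhip, 4.32 and 7.30 CPM, than those in it. RNA from other cells is argued against rather by the mutant. There Gli1, Ptch1 and Hhip stood at 4.44, 24.1 and 3.18 CPM outside the epithelium, against 20.0, 184 and 14.8 CPM in it. A difference between the libraries as a whole would need a like median in mesenchyme, where it was -0.0494. The mesenchymal value argues against that explanation. Loss of Ptch1 in cells that express Emx2 remains a hypothesis: the highest median among compared classes with Emx2 under 1 CPM was -0.0494, against 2.57 in the epithelium. The former is the value of Gli1 and the latter that of Ptch1 itself. Genotype and library cannot be separated by replication in this design, and the hypothesis was formed on the same data.

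For the lower hair cell genes, the 10 fixed hair cell markers had a median of -1.49 in all epithelial barcodes. RNA from other cells in wild-type barcodes would need the median to come within 2-fold without mixed barcodes, and it was -1.66 (95% counting interval -1.98 to -1.46). That test could hardly come out otherwise for markers rare in other cells. Outside the wild-type epithelium Pou4f3, Atoh1, Ccer2 and Rasd2 stood at 0.229, 0.0763, 4.60 and 1.53 CPM. These low values argue against other cells as the source of those markers. Myo6 and Pvalb stood higher outside the wild-type epithelium than in it, at 97.7 and 106 CPM, so for them this stays open. Fewer hair cells recovered by dissection or digestion cannot be told apart from fewer hair cells in the tissue: hair cell-like barcodes were 0.0968% of the mutant epithelium, and no measure of recovery separates these cases. The genotype stays open as an untested explanation.

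Histone and other genes differed alike in several classes. Of the 10 genes named in mesenchyme, 8 were measured in glia, where all had the same direction and 7 had log2 ratios within 1 of those in mesenchyme. In epithelium 6 of the 10 did. Loss of Ptch1 within cells that express Emx2 at E16.5 is argued against for these genes, since mesenchyme and glia had Emx2 under 1 CPM. Earlier Emx2 expression in these classes and effects passed on from other cells were not tested, so the genotype is not excluded. A difference between the libraries as a whole, such as the software version or kit, stays open: the test asked for 8 of 10 genes, which the genes without a glial value put almost out of reach, so the count of 7 is no evidence against it. Strain makeup was not tested.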

How the results depend on the processing

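The limits on mixed barcodes and the common UMI floor were chosen after seeing the data, and the cause of no move listed here was tested. Over all alternatives the epithelial medians ranged from 1.76 to 3.27 for the Hedgehog core, -0.96 to -0.25 for the sensory list, 0.29 to 0.63 for the roof list, 0.24 to 1.27 for S phase and 0.53 to 1.50 for G2 and M phase, each keeping its direction. The Hedgehog target median depended on which members were measured and how barcodes were chosen, and the marginal median reversed when shared sub-clusters were weighted alike. That weighting used 513 of 1705 wild-type barcodes, 282 of them in a sub-cluster led by mesenchymal genes. It left out the hair cell-like and lateral sub-clusters and the one nearest to marginal cells, so its values say nothing about those cells. The wild-type epithelial share moved under every alternative, and it was below the mutant share at Leiden 2 (20.0% and 23.4%), with genes centred per library, and with mixed sub-clusters left out. Values outside the main counting interval follow by setting, as list medians and shares. With all deposited barcodes: Hedgehog targets -0.0632, G2 and M phase 0.89, wild-type epithelial share 25.1% and mutant epithelial share 24.9%. With at least 2000 UMIs and 1000 genes and at most 5% mitochondrial: Hedgehog targets -0.16, mesenchymal Hedgehog core 0.24, S phase 1.02, G2 and M phase 1.37, wild-type epithelial share 22.4%, mutant epithelial share 16.1% and mutant marginal transcript share 0.123%. With doublets kept: Hedgehog targets -0.0565, wild-type epithelial share 26.6% and mutant marginal transcript share 0.265%. At Leiden 0.5: Hedgehog targets -0.0761 and wild-type epithelial share 24.7%. At Leiden 2: Hedgehog targets -0.23, Hedgehog core 2.90, roof 0.39, S phase 0.89, G2 and M phase 1.23, wild-type epithelial share 20.0% and mutant marginal transcript share 0.147%. With genes centred per library: Hedgehog targets -0.0930, roof 0.48, G2 and M phase 1.14 and wild-type epithelial share 23.6%. Above the common UMI floor: G2 and M phase 1.15, wild-type epithelial share 23.6%, mutant epithelial share 15.5% and mutant marginal transcript share 0.185%. Without sub-clusters led by other classes: Hedgehog targets -0.35, Hedgehog core 3.01, roof 0.34, S phase 1.17, G2 and M phase 1.47, wild-type epithelial share 16.3% and wild-type marginal transcript share 3.52%. With median-of-ratios scaling: Hedgehog targets -0.0726, roof 0.48 and G2 and M phase 0.91. With members of at least 50 UMIs: Hedgehog targets 0.47 and sensory -0.44. With each cell weighted alike: Hedgehog targets -0.27, Hedgehog core 2.09, marginal -0.78, roof 0.34 and G2 and M phase 0.84. In cells with Epcam or Cdh1: Hedgehog targets 0.38, Hedgehog core 2.20, marginal -0.20, roof 0.29, sensory -0.29, S phase 0.58 and G2 and M phase 0.75. With shared sub-clusters weighted alike: Hedgehog targets 0.74, Hedgehog core 1.76, marginal 0.10, sensory -0.25, S phase 0.24 and G2 and M phase 0.53. Without barcodes over 5 other-lineage UMIs per 10000: Hedgehog targets 0.46, Hedgehog core 3.27, roof 0.49, sensory -0.96, S phase 1.27, G2 and M phase 1.50, intermediate cell 0.0422 and wild-type marginal transcript share 1.08%. Without those over 10 per 10000: Hedgehog targets -0.21, Hedgehog core 2.99, roof 0.40, sensory -0.95, S phase 1.07 and G2 and M phase 1.43. With a pseudocount of 5 CPM: Hedgehog core 1.84, marginal -0.25, sensory -0.35 and S phase 0.72. With all detected members: marginal -0.33. Thinned to 4000 UMIs: wild-type marginal transcript share 4.44%. Unthinned: wild-type marginal transcript share 7.51% and mutant marginal transcript share 1.55%. No paired analysis was possible because each genotype has 1 library.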

Other observations

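The comparisons without mixed barcodes were chosen only after the results had been seen. Members of the signalling lists went both ways in mutant epithelium. Fgf9 stood at 20.2 and 53.3 CPM in wild type and mutant, and Etv5, a transcription factor induced by the pathway, at 25.8 and 65.3 CPM, while Fgf8, made by inner hair cells, stood at 5.69 and 0.985 CPM. The FGF list had a median of 0.22 (95% counting interval 0.11 to 0.39, percentile 95.2 of matched random lists), with 3 members at least 2-fold higher and 4 at least 2-fold lower. BMP pathway genes had a median of -0.49 (95% counting interval -0.55 to -0.36, percentile 0.005 of matched random lists), and Notch pathway genes of -0.11 (95% counting interval -0.22 to 0.00727, percentile 7.03 of matched random lists). WNT genes had a median of -0.16 (95% counting interval -0.25 to -0.00200, percentile 1.56 of matched random lists), with Wnt4 at 9.54 and 32.7 CPM and Lef1 at 30.5 and 8.28 CPM. Otic transcription factors had a median of 0.36 (95% counting interval 0.31 to 0.50, percentile 99.99 of matched random lists), with Pax2 at 8.85 and 28.5 CPM. Retinoic acid genes had a median of -0.15 (95% counting interval -0.31 to -0.0286, percentile 7.09 of matched random lists), with the degrading enzyme Cyp26a1 at 2.53 and 11 CPM. Without mixed barcodes the medians were 0.33 for FGF, -0.39 for BMP, -0.17 for Notch, -0.14 for WNT, 0.14 for otic transcription factors and 0.0304 for retinoic acid genes.

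Lists tied to handling and mixing also differed in the epithelium. Dissociation stress genes had a median of -0.44 (95% counting interval -0.56 to -0.36, percentile 0 of matched random lists), with Fos at 709 and 350 CPM in wild type and mutant. The same list was also lower in mesenchyme, at -0.15, and in glia, at -0.24. Median mitochondrial shares of kept barcodes were 2.39% in the wild type and 4.27% in the mutant. Hypoxia and glycolysis genes had a median of -0.24 (95% counting interval -0.31 to -0.10, percentile 1.23 of matched random lists), and barrier genes of 0.0638 (95% counting interval 0.00517 to 0.12, percentile 57.5 of matched random lists). Extracellular matrix genes had a median of -0.55 (95% counting interval -0.75 to -0.40, percentile 0 of matched random lists), mesenchyme transition genes of -0.27 (95% counting interval -0.37 to 0.0809, percentile 0.79 of matched random lists) and intermediate cell genes of -0.54 (95% counting interval -0.70 to -0.25, percentile 0.26 of matched random lists). With mixed barcodes left out, the stress, hypoxia and barrier medians were -0.49, -0.30 and -0.10, and the later ones were -0.30, -0.10 and -0.39. Haemoglobin genes had a median of -5.00, and -1.86 without mixed barcodes. Sex chromosome genes had a median of 0.24, and 0.0844 without mixed barcodes.

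Mixed wild-type epithelial barcodes had fewer UMIs than the others, with medians of 6545 and 8680.5. Their median doublet scores were 0.0573 and 0.0330. Haemoglobin made up 71.0% of UMIs in wild-type erythroid barcodes and 90.5% in mutant ones, and 0.0142% in wild-type mesenchyme.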
